A study of Mus musculus with 12 samples.

How the data were processed

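RNA from 12 cultures of PUER cells was hybridized to 12 one-colour mouse microarrays carrying probes for most annotated genes. PUER is a myeloid line derived from cells lacking the transcription factor PU.1; it carries a fusion of PU.1 with the ligand-binding part of the estrogen receptor and grows in the cytokine IL-3. The drug 4-hydroxytamoxifen (4-OHT) activates the fusion protein, and the cells then mature. Per the labels, cells carried either a control retroviral vector or a vector with a short hairpin RNA (shRNA) against Hnrnpa0, were sorted on the vector's GFP marker, and were collected before 4-OHT or after 24 h in 2 nM 4-OHT. Each of the 4 groups holds 3 arrays (replicates A, B and C), from separate clones per vector. The protocol mentions vehicle, but the labels name no array of cells kept in it.

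Per the file headers, the authors scanned the arrays (design 014868) and read them with Agilent Feature Extraction 9.5.3.1, which the submitters' processing notes give as 9.5. The deposited values are linear Cy3 intensity per spot after detrending and background subtraction, and they carry no scaling between arrays. The deposited summary table holds the same intensity values rounded, within 0.497% of the scanner output on each array. Slide identity came from the file headers: slide 1 held the 3 control arrays before 4-OHT and control replicate A after it; slide 2 held control replicates B and C after 4-OHT and shRNA replicates A and B before it; slide 3 held shRNA replicate C before 4-OHT and the 3 shRNA arrays after it. The vectors therefore shared no slide within a treatment.

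Control spots and spots marked as outliers by the scanner software were left out, spots of a probe were averaged, and log2 intensity was taken relative to each array's 75th percentile, which lay between 1196 and 2583. Between 50.3% and 55.7% of the spots on an array were well above background. Of 41174 probes, 23075 were named through transcript identifiers, 6582 through a current symbol and 3077 through an older symbol in the mouse gene reference; the other 8440 kept the name in the scanner output. Genes were tested on 1 probe each, the one of highest mean, if well above background on at least 3 of the 12 arrays and present on at least 2 arrays of each group. This left 15063 genes. Probe positions are those of the array design on mouse build mm7. The number of arrays limits the precision of every value.

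limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8) was fitted to all 12 arrays with 4 group means (lmFit, eBayes), and 5 contrasts were taken: 4-OHT against before in each vector, shRNA against control before and after 4-OHT, and the difference between the 4-OHT responses (interaction). Adjusted p is by Benjamini-Hochberg over the 15063 genes, with a threshold of 0.05, and SE is that of the fit. Levels are given as mean with SD. Hnrnpa0 also had an exact two-sided permutation test of vector within treatment. A fold against a group below background is a lower bound, computed from the lowest signal well above background on each array, and so is a fold where the brighter spots were saturated; both are written as "at least". List medians with bounds leave out members without a usable bound, such as those saturated in both groups or under background in both. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

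There were 25 gene lists: monocyte and macrophage, neutrophil primary granule, late granulocyte, PU.1-activated, stem and progenitor, mast cell and basophil, eosinophil, erythroid, megakaryocyte, T cell, B cell, dendritic cell and MHC class II, G1/S, G2/M, ribosome biogenesis and Myc target, AU-rich element cytokine and immediate early, AU-rich element binding and hnRNP protein, orthologues of human 5q genes, interferon, p53 target, unfolded protein and integrated stress response, heat shock, cholesterol synthesis, lysosome, and glycolysis and hypoxia. Each was tested with limma's camera at a preset correlation of 0.01 over the 14373 genes with a value on every array, adjusted over the 25 lists of a contrast. The shift of a list is the mean log2 change of its members less that of the other genes. Estimated correlations and fry were alternatives. The estimate was -0.0098 for the monocyte and macrophage list and -0.024 for the stem and progenitor list, both below the preset. A higher p of these lists under that alternative therefore does not come from correlation among their members. A test of transcripts by AU-rich motifs in their 3' untranslated regions was planned and not run, since no untranslated sequence was available.

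Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule takes, per contrast, the 6 largest rises and 6 largest falls among genes past the threshold whose groups of 3 arrays do not overlap whose brighter group is well above background and whose name is not that of an unnamed transcript, ordered by fold with bounds in place of unmeasured folds, or, for the interaction, the 4 of smallest p if none pass; up to 4 members of smallest p per list discussed; and 17 genes in every contrast (Hnrnpa0, Spi1, Csf1r, Itgam, Adgre1, Cd14, Mpo, Elane, Gfi1, Cebpe, Csf3r, Cebpa, Kit, Myc, Egr1, Egr2, Esr1). Cebpe has no probe, and Egr1 was not tested because its probe was marked as an outlier on 3 arrays. Some genes that the rule selects are not reported here. A gene outside the rule is said to be chosen after its values were seen. Alternatives covered scaling, background, filters, floor, outlier spots, probes, slide, replicate block, the arrays in the fit, variance model, array weights, leaving out each array, the deposited summary table, and a threshold of 2-fold; a correction for probe GC content and signal, and list tests over genes above background on all 12 arrays, were added after seeing the data. The procedure was tested on simulated data built from the gene means and residual spreads of 14373 genes with 200 changed genes per contrast: of 100 genes changed 2-fold, 81 were recovered in shRNA against control before 4-OHT, 76 after it, and 63 in the interaction, with 3, 7 and 4 calls among unchanged genes. Of 100 genes changed 1.5-fold, 45, 64 and 26 were recovered. The simulated arrays vary independently, with no slide or clone effect, so the few false calls do not cover a slide difference between the vectors.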

Results

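Expression was measured on 12 arrays from PUER cells, 3 in each combination of vector (control or Hnrnpa0 shRNA) and treatment (before or 24 h after 4-OHT), to learn how loss of Hnrnpa0, a gene of the region deleted in del(5q) myeloid disease, alters myeloid maturation. Across genes, arrays of the same group correlated with r between 0.990 and 0.996, and arrays of different groups with r between 0.954 and 0.993; genes are not independent replicates. The first principal component held 68.6% of the variance and parted the arrays by 4-OHT. The second held 9.51% and placed all 6 shRNA arrays below all 6 control arrays, with shRNA replicate C before 4-OHT (score -28.78) apart from replicates A and B (-3.69 and -11.14). Replicate C of that group was on slide 3, and A and B were on slide 2.

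**Figure D1:**
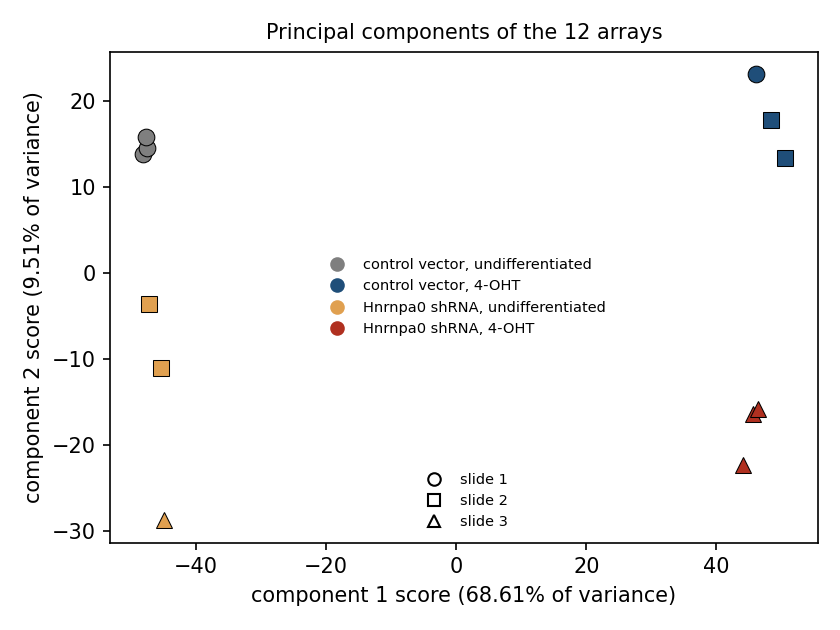
Scores of the 12 arrays on the first and second principal components (68.6% and 9.51% of the variance), coloured by group, with the marker shape giving the slide. The first component runs from about -48.24 to 50.59 and parts the arrays by 4-OHT.

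Hnrnpa0, which encodes an RNA-binding protein that recognises AU-rich elements, was measured first because the shRNA targets it. Its brighter probe (A_51_P517423, chromosome 13, 57219687 to 57219746) read 3.05 ± 0.07 (log2, SD, n = 3) in control cells before 4-OHT and 2.65 ± 0.07 after it, against 1.502 ± 0.47 and 0.55 ± 0.09 in shRNA cells. The log2 difference between vectors was -1.54 (SE 0.18, adjusted p = 0.0127) before 4-OHT and -2.10 (SE 0.18, adjusted p = 0.00511) after it, which left 34.3% and 23.3% of the control signal. The dimmer probe (57220223 to 57220282) gave -1.37 and -1.94. Both probes were lower in all 6 shRNA arrays than in any control array, and the exact two-sided permutation p was 0.005 for each, the smallest the 400 relabellings can give. The permutation treats all arrays as independent, although arrays before and after 4-OHT may come from the same clone. It also takes no account of slide, which the vectors did not share within a treatment. With slide as a fixed block the difference was -1.38 at both times, with adjusted p = 0.114 before and 0.0897 after 4-OHT. The call for the Hnrnpa0 level before 4-OHT also ended without control replicate B (adjusted p = 0.0652), control replicate C (0.0691) or shRNA replicate B (0.0537). Under 4-OHT itself Hnrnpa0 fell in shRNA cells (-0.95, adjusted p = 0.00193) and did not pass in control cells (-0.39, adjusted p = 0.112). Within a slide the change was -0.45 in shRNA cells (slide 3) and -0.45 in control cells (slide 1), each with 1 array in an arm. The difference between the responses over all arrays was -0.55 (SE 0.26, adjusted p = 0.943).

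**Figure D2:**
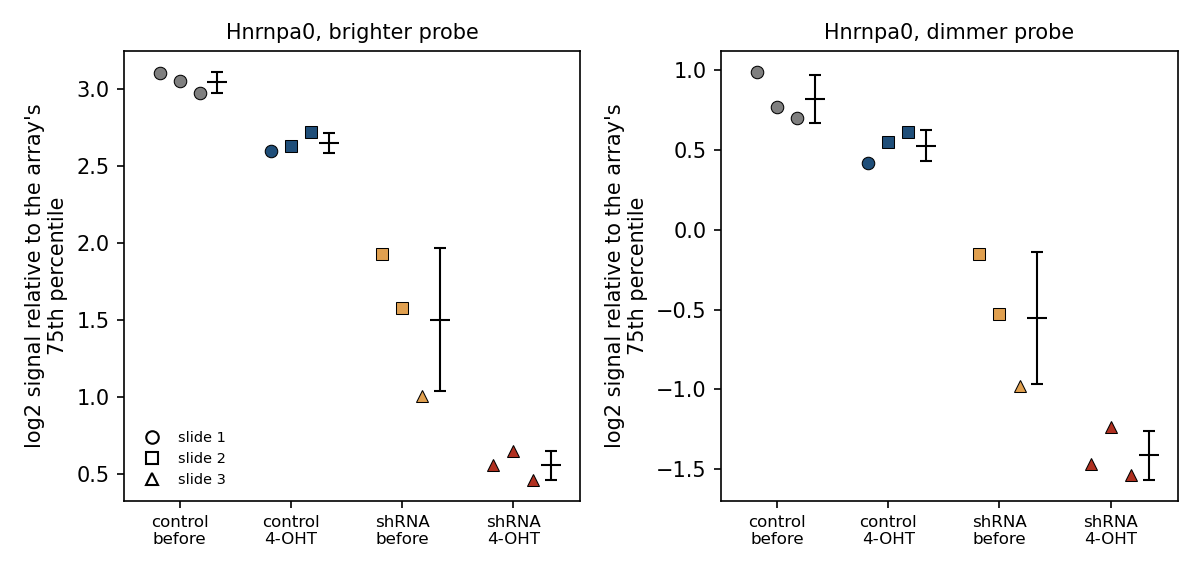
Hnrnpa0 signal on each array for its brighter and dimmer probe, as log2 relative to the array's 75th percentile; marker shapes give the slide, and bars the mean with SD of 3 arrays. The brighter probe averages 3.05 and 2.65 in control cells and 1.502 and 0.55 in shRNA cells.

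The response of control cells to 4-OHT addresses what activation of the PU.1 fusion does in this line; effects of the drug itself or of 24 h in culture are not separated from it. By the rule for named genes, the largest rises were in surface receptors of myeloid cells and in genes of the Bcl2a1 family. The receptors were the C-type lectins Clec4b1 (at least 389-fold, log2 8.71, SE 0.25), Clec4a2 (367-fold) and Clec4n (135-fold), and the immunoglobulin-like Lilra6 (at least 274-fold). The family members were Bcl2a1b (at least 188-fold) and Bcl2a1c (at least 135-fold). Among the largest falls were those of the membrane protein gene Tmem119 (90.3-fold, log2 -6.50, SE 0.11), Glod5 (27.2-fold), the adhesion adaptor Bcar1 (17.5-fold), and Dock9 and Rapgef3 (15.4-fold and 15.0-fold), exchange factors of small GTPases. Each of these genes kept its 3 arrays of one group clear of the 3 of the other, a separation that chance gives 10% of genes.

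Monocyte and macrophage genes rose as a group in control cells: of 33 measured, 25 rose, 2 fell and 6 did not pass, with the same 25 and 2 when adjusted over the list alone. The integrin Itgax rose at least 15.0-fold, the macrophage elastase Mmp12 at least 14.0-fold, the F4/80 antigen Adgre1 at least 5.83-fold, and the pore-forming Mpeg1 34.2-fold. Itgam, the CD11b integrin, rose 5.22-fold (log2 2.38, SE 0.14, n = 3 per group), and Csf1r, the macrophage colony-stimulating factor receptor, rose at least 2.64-fold. Cd14 rose at least 2.96-fold, and Egr2, a transcription factor of macrophage differentiation, 7.04-fold. Apoe (-0.68) and Ly6c1 (-0.74), named after their values were seen, were the 2 that fell. The list's median log2 change was 1.23, and 1.31 with dim genes at their bounds (camera adjusted p = 4.88e-16, and adjusted p = 0.000259 with an estimated correlation).

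Of 26 genes known to be activated by PU.1, 17 rose, 4 fell and 5 did not pass in control cells (18 and 4 adjusted over the list alone). The cytokine Il18 rose 62.4-fold, the cytokine Tnf by 2.73 in log2, and the Fc receptor Fcgr1 and scavenger receptor Msr1 at least 21.5-fold and 5.68-fold. The median was 0.88, and 1.16 with bounds (camera adjusted p = 1.96e-07, and adjusted p = 0.0247 with an estimated correlation). The 4 that fell, named after their values were seen, were Csf3r (-0.56), the oxidase subunits Ncf1 (-0.70) and Ncf4 (-1.23), and Vav1 (-0.33). The signal of the Spi1 probe, the gene of PU.1, fell by 0.59 (SE 0.10, adjusted p = 0.000845), and that of Esr1 fell by 0.78 (SE 0.11, adjusted p = 0.000179); whether these probes read the fusion transcript is not known. Of 29 lysosome genes, 16 rose and 3 fell (the same adjusted over the list alone), among them the mannosidase Man2b1 (2.67-fold), the lipase Lipa (3.17-fold), Gusb (1.67-fold) and the proton pump subunit Atp6v0d2 (2.92-fold) upward. Those that fell, named after their values were seen, were Gaa (-0.41), Tpp1 (-0.33) and Acp5 (-2.45) (median 0.39, and 0.40 with bounds; camera adjusted p = 0.00683, and adjusted p = 0.192 with an estimated correlation). Of 6 eosinophil genes, 5 rose (also adjusted over the list alone), including the ribonuclease Ear1 (at least 1.31-fold) and the granule protein Prg2 (at least 5.33-fold); none was above background in both groups (median 1.64, and 0.39 over the 3 with a bound; camera adjusted p = 0.0110, and adjusted p = 0.318 with an estimated correlation).

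Progenitor and early granulocyte genes fell in control cells. Of 19 stem and progenitor genes, 14 fell, none rose and 5 did not pass (15 fell adjusted over the list alone): the stem cell factor receptor Kit 3.79-fold, the transcription factors Hlf 4.15-fold and Myb 2.77-fold (1 of its 3 other probes had the opposite sign), and the surface antigen Ly6a 3.79-fold. Their median was -0.86, the same with bounds (camera adjusted p = 1.79e-06, and adjusted p = 0.00692 with an estimated correlation). Of 14 neutrophil primary granule and early granulocyte genes, 8 fell and 1 rose (the same adjusted over the list alone). The repressor Gfi1, required for granulocyte formation, went from 4.99 ± 0.03 to 2.55 ± 0.11 (log2, SD, n = 3), at least 5.42-fold. Nkg7 fell 6.51-fold, the neutrophil elastase gene Elane 3.42-fold, and the transcription factor Cebpa 1.95-fold. Igsf6, a membrane protein of myeloid cells, rose at least 4.53-fold. Csf3r, the granulocyte colony-stimulating factor receptor, fell by 0.56, Myc fell by 0.50, and the saturated Mpo probe differed by 0.03 (adjusted p = 0.928). The list's median was -0.76, and -1.50 with bounds and without saturated genes (camera adjusted p = 0.00917, and adjusted p = 0.422 with an estimated correlation).

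Metabolic genes fell as well. Of 23 cholesterol synthesis genes, 19 fell and none rose (20 adjusted over the list alone), among them Tm7sf2 (2.20-fold), Stard4 (1.66-fold), Hsd17b7 (1.97-fold) and Nsdhl (1.92-fold). The median was -0.67, and -0.73 with bounds (camera adjusted p = 1.15e-06, and adjusted p = 0.192 with an estimated correlation). Of 22 glycolysis and hypoxia genes, 13 fell and none rose (also 13 adjusted over the list alone), with the prolyl hydroxylase Egln3 falling at least 9.45-fold, Bnip3 at least 5.10-fold, Vegfa 4.46-fold and the carbonic anhydrase Car9 8.21-fold (median -0.68, and -1.05 with bounds; camera adjusted p = 1.75e-05, and adjusted p = 0.192 with an estimated correlation). Of 17 genes of the unfolded protein and integrated stress responses, 10 fell and none rose (also 10 adjusted over the list alone), including Trib3 (2.78-fold), Xbp1 (1.63-fold), Ddit4 (at least 2.27-fold) and the chaperone Dnajb9 (1.87-fold). The median was -0.45, and -0.53 with bounds (camera adjusted p = 0.00683, and adjusted p = 0.192 with an estimated correlation). In all, 6102 of 15063 genes passed in control cells, 2631 higher and 3471 lower, 1567 of them by at least 2-fold; the median over all genes was -0.07. With slide as a fixed block 5467 passed, 4502 of them shared. Within slide 1, which held 3 control arrays before and 1 after 4-OHT, 3470 genes passed; these arrays are among those that gave the 6102 genes, and the lone array is assumed to vary like the others.

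**Figure D3:**
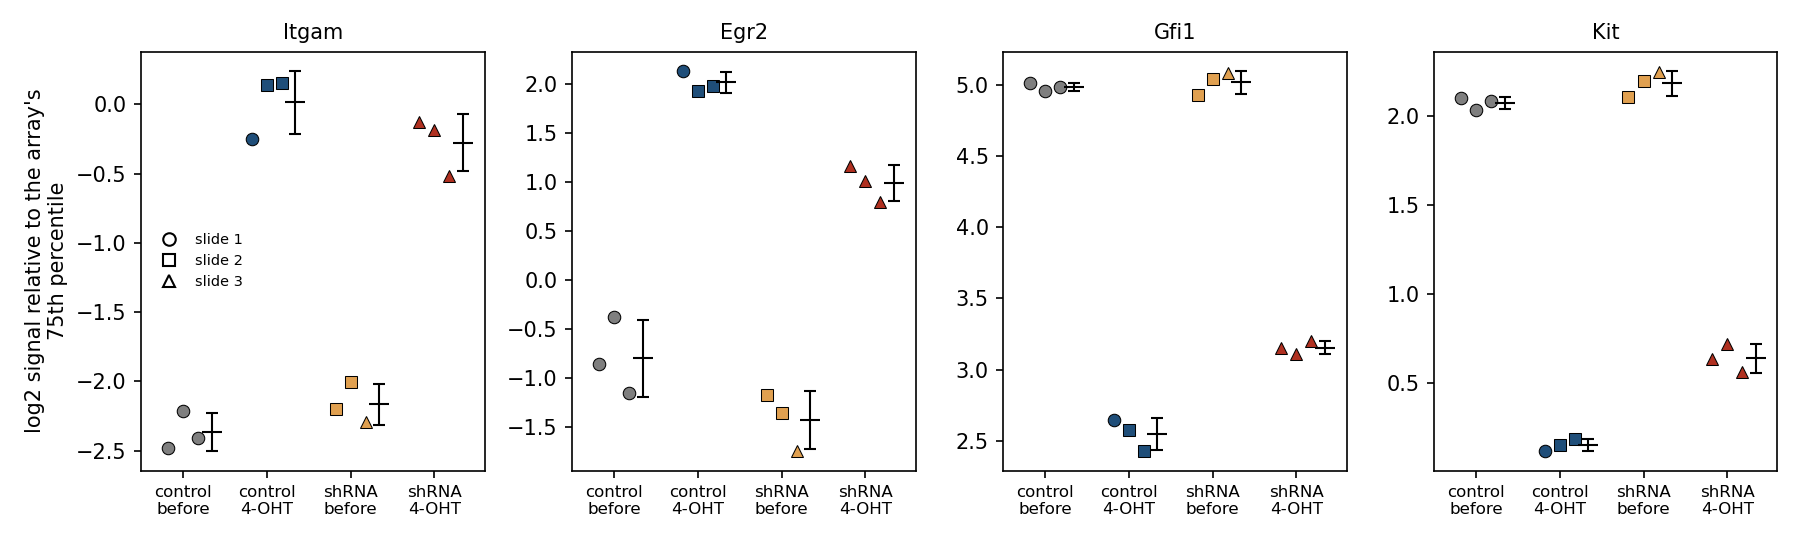
Signal of Itgam, Egr2, Gfi1 and Kit on each array, as log2 relative to the array's 75th percentile; marker shapes give the slide, and bars the mean with SD of 3 arrays. After 4-OHT, Gfi1 averages 2.55 in control and 3.15 in shRNA cells, and Egr2 2.02 and 0.99.

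In shRNA cells 4-OHT produced much the same list of leading genes. Clec4b1 rose 362-fold, Clec4a2 at least 223-fold, Lilra6 at least 185-fold, Bcl2a1c at least 145-fold, Bcl2a1b at least 143-fold and Clec4n 110-fold. Tmem119 fell 95.6-fold, Bcar1 26.5-fold, Glod5 21.1-fold, the mitochondrial folate enzyme Aldh1l2 at least 17.3-fold and the transglutaminase Tgm2 14.9-fold. Of 33 monocyte and macrophage genes, 25 rose and none fell (25 and 1 adjusted over the list alone), among them Itgax (at least 16.1-fold), Mmp12 (at least 11.5-fold) and Adgre1 (at least 5.88-fold). The median was 1.36, and 1.55 with bounds (camera adjusted p = 5.13e-16, and adjusted p = 0.000261 with an estimated correlation). Of 26 genes activated by PU.1, 15 rose and 3 fell (camera adjusted p = 1.14e-06, and adjusted p = 0.0352 with an estimated correlation). Itgam rose 3.71-fold, Csf1r at least 3.77-fold, Cd14 at least 2.57-fold and Egr2 5.34-fold.

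Of 19 stem and progenitor genes 15 fell and none rose in shRNA cells (camera adjusted p = 1.58e-06, and adjusted p = 0.00672 with an estimated correlation), Kit 2.92-fold among them. Gfi1 fell at least 3.64-fold, Elane 2.92-fold and Cebpa 1.80-fold. Csf3r fell by 0.34, Myc fell by 0.65, Spi1 fell by 0.42 and Esr1 fell by 0.75. The primary granule, eosinophil, stress response, cholesterol, lysosome and glycolysis lists also passed with the direction seen in control cells, and none of these held with an estimated correlation (adjusted p = 0.415, 0.271, 0.226, 0.257, 0.271 and 0.192 in that order). Another 2 lists passed. AU-rich element cytokine and immediate early genes were lower, with 17 of 30 falling and 3 rising (18 and 4 adjusted over the list alone): Vegfa fell 4.51-fold and Ier3 3.28-fold, and the cytokine Tnf rose 6.27-fold and the adhesion molecule Icam1 at least 3.61-fold (median -0.55, and -0.65 with bounds; camera adjusted p = 0.00513, and adjusted p = 0.226 with an estimated correlation). G2/M genes were higher, with 6 of 34 rising and none falling, 4 adjusted over the list alone (median 0.16, the same with bounds; camera adjusted p = 0.0193, and adjusted p = 0.528 with an estimated correlation, and 0.0584 with slide as a fixed block). In all, 5770 genes passed, 2481 higher and 3289 lower, 1436 by at least 2-fold, with a median over all genes of -0.08. With slide as a fixed block 4618 passed, 4084 of them shared; within slide 3 (1 array before, 3 after), under the same limits, 2639 genes passed.

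Before 4-OHT few genes passed the threshold between shRNA and control cells, and Hnrnpa0, the intended one, was among them. By the rule for named genes, the largest rises in shRNA cells were in the ferritin-like Fthl17e (3.03-fold, log2 1.60, SE 0.27), the milk protein gene Lalba (2.84-fold), the zinc finger gene Zfp652 (2.46-fold), the heparan sulfate sulfotransferase Hs6st3 (1.90-fold), the sugar transporter Slc2a6 (1.62-fold) and the transcriptional regulator Arid5b (1.51-fold). By the same rule, which leaves out unnamed transcripts and genes under background, the largest falls besides Hnrnpa0 (2.92-fold) were in the bicarbonate transporter Slc4a7 (5.16-fold, log2 -2.37, SE 0.33), Prr15 (1.95-fold), Arhgap26 (1.86-fold), Tial1 (1.77-fold), which encodes a protein that binds AU-rich elements, and the galactosyltransferase B4galt1 (1.75-fold). The second Tial1 probe and 1 of the 2 other Arhgap26 probes had the opposite sign. Slc4a7 fell more than Hnrnpa0 itself. The labels name no other shRNA, so effects of less Hnrnpa0 are not set apart from other effects of the shRNA vector or its clones. The stem cell list member Zfpm1 fell 1.36-fold. None of the 25 lists passed camera (lowest adjusted p = 0.250), and none did with an estimated correlation or by fry.

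Myeloid regulators did not pass between the vectors before 4-OHT: Gfi1, saturated in both groups, differed by 0.03, Kit by 0.11, Cebpa by 0.19, Csf3r by 0.11, Myc by -0.23, Egr2 by -0.63 (adjusted p = 0.122), Itgam by 0.20, Cd14 by -0.19, Elane by 0.07, Mpo by 0.01, Spi1 by -0.07, Esr1 by -0.36, and the tested probes of Adgre1 and Csf1r, both under background on these arrays, by -0.34 and 0.86. Another Adgre1 probe was above background but not tested, because of outlier marks after 4-OHT. In all, 57 genes passed, 22 higher and 35 lower, 10 by at least 2-fold, with a median over all genes of -0.03. At an unadjusted limma p under 0.05 there were 3361. Since the filter takes any 3 of the 12 arrays, the 57 can hold genes under background before 4-OHT, such as Klra2, chosen after its values were seen. With slide as a fixed or a random block no gene passed limma's threshold (2526 and 2083 at an unadjusted p under 0.05); with the fixed block all 57 kept their direction, at a median of 0.847 of their size. No slide held both vectors before 4-OHT, so no within-slide value can be had. The count was 394 with quantile normalization (38 higher) and 2 with normexp background (Hnrnpa0 and Slc4a7). It was 169, of which 60.9% were higher, with a trend on probe GC content and signal removed, which was chosen after seeing the data. It was 32, 4 (Prr15, Txndc16, Klra2 and 1 unnamed transcript, chosen after their values were seen) and 0 without control replicate A, B or C before 4-OHT, 309 and 12 without control replicate A or B after it. It was 496, 1 (Tifab, named likewise) and 13 without shRNA replicate A, B or C before it, and 26 and 19 without shRNA replicate A or B after it.

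After 4-OHT, some macrophage genes were lower and some progenitor and granulocyte genes higher in shRNA than in control cells, by small amounts. No gene called between the vectors after 4-OHT, Hnrnpa0 included, kept its call with slide as a fixed or a random block. Gfi1 was 1.52-fold higher (3.15 ± 0.04 against 2.55 ± 0.11, log2, SD, n = 3; adjusted p = 0.00740), Kit 1.40-fold higher (adjusted p = 0.00740), Cebpa 1.24-fold (adjusted p = 0.0223) and Csf3r 1.26-fold (adjusted p = 0.0483). Egr2 was 2.04-fold lower (0.99 ± 0.18 against 2.02 ± 0.11; adjusted p = 0.0158), and the saturated Cd14 probe differed by -0.40 (adjusted p = 0.0428). Itgam (-0.29), Adgre1 (-0.38, adjusted p = 0.0549), Csf1r (0.13), Elane (0.30), Mpo (-0.30), Myc (-0.38), Spi1 (0.10) and Esr1 (-0.33) did not pass. By the rule for named genes, the largest rises were in the connexin Gjd3 (2.83-fold), Fthl17e (2.81-fold), Sema6a (at least 2.40-fold), the adhesion molecule Ceacam1 (2.37-fold), Rgs8 (2.31-fold) and the homeobox gene Six4 (2.15-fold). By the same rule the largest falls were in Hnrnpa0 (4.28-fold), Slc4a7 (4.10-fold), the aspartyl-tRNA synthetase Dars (3.03-fold), the potassium channel Kcnj2 (2.71-fold), the transcription factor Mitf (2.65-fold) and Bco2 (at least 2.58-fold). The Gjd3 difference was -0.30 (adjusted p = 0.952) with slide as a fixed block.

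Of 33 monocyte and macrophage genes, 7 were lower, 1 higher and 25 did not pass after 4-OHT (10 and 1 adjusted over the list alone). Mmp12 was 1.59-fold, the signal regulator Sirpa 1.45-fold and the endotoxin receptor Tlr4 1.38-fold lower. For Sirpa, 1 of 2 other probes had the opposite sign, and the 1 higher gene was Gpnmb, named after its values were seen. The median was -0.25, and -0.24 with bounds (camera adjusted p = 0.0330, and adjusted p = 0.239 with an estimated correlation). Of 30 AU-rich element cytokine and immediate early genes 6 were lower and none higher (8 and none adjusted over the list alone), among them Jun (1.40-fold), the urokinase receptor Plaur (1.32-fold), the phosphatase Dusp1 (1.56-fold) and the chemokine Ccl4 (1.58-fold). The median was -0.21, and -0.20 with bounds (camera adjusted p = 0.00984, and adjusted p = 0.371 with an estimated correlation). Of 30 genes of AU-rich element binding and hnRNP proteins, a list that holds Hnrnpa0 itself, 6 were lower and none higher (also 6 adjusted over the list alone), including Elavl1 (1.45-fold), Tial1 (1.67-fold, with its second probe past the threshold in the opposite direction) and Hnrnpa2b1 (-0.44, saturated). The median was -0.25 (camera adjusted p = 0.0330, and adjusted p = 0.762 with an estimated correlation). It was -0.07 over the 20 members left with bounds, although 29 were above background in both groups. Members saturated in both groups are not among the 20, so the lower value rests largely on saturated probes.

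Lists that did not pass camera after 4-OHT held genes past the threshold too. Of 19 stem and progenitor genes 5 were higher and 2 lower (8 and 4 adjusted over the list alone): Hlf 1.64-fold and Ly6a 1.66-fold higher, Zfpm1 1.38-fold and, named after its values were seen, Angpt1 lower (camera adjusted p = 0.113). Of 14 primary granule genes 4 were higher and none lower (6 and 1 adjusted over the list alone), with the protease inhibitor Cst7 1.34-fold higher (camera adjusted p = 0.243). Of 26 genes activated by PU.1, 6 were lower and 3 higher (9 and 3 adjusted over the list alone), with Il18 1.31-fold lower and the oxidase subunit Ncf1 1.60-fold higher (camera adjusted p = 0.243). Of 18 p53 targets 5 were lower and none higher (8 and none adjusted over the list alone), including Phlda3 (1.54-fold), the pro-apoptotic Bbc3 (1.46-fold) and Bax (1.34-fold), and the death receptor Fas (1.27-fold; camera adjusted p = 0.107). Of 23 cholesterol synthesis genes 5 were higher and none lower, Nsdhl (1.44-fold), Lss (1.43-fold), Cyp51 (1.26-fold) and Dhcr7 (1.29-fold) among them (camera adjusted p = 0.347). With slide as a fixed block 6 lists passed camera: the monocyte and macrophage (adjusted p = 0.0154), AU-rich element cytokine (0.0460), primary granule (0.0154), stem and progenitor (0.0159), p53 target (0.0154) and cholesterol (0.0452) lists, while the AU-rich element binding and hnRNP list did not (0.245). An estimated correlation was run only without the block, where none of the 25 lists passed. In scores per array with the block, only the monocyte and macrophage list of these 6 differed by more than 2 SE (-0.20, SE 0.05). Over members above background on all 12 arrays the monocyte difference was -0.11 (SE 0.05). There the stem and progenitor (0.18, SE 0.06) and p53 target (-0.13, SE 0.05) lists also differed by more than 2 SE, and the rest of the 6 did not. Camera with the block then passed the stem and p53 lists (adjusted p = 0.0172 each) and not the monocyte list (0.0880).

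In all, 2512 genes passed after 4-OHT, 1183 higher and 1329 lower, 96 by at least 2-fold (22 higher and 74 lower), with a median over all genes of -0.04. With slide as a random block no gene passed limma's threshold (2615 at an unadjusted p under 0.05). With slide as a fixed block 1 gene passed, which was not among the 2512. At an unadjusted limma p under 0.05 that block gave 912 genes, fewer than the 2526 before 4-OHT. Of the 2512, 94.5% kept their direction with it, and the median size was 0.430 of that without it. The 1 gene was Foxred2 (1.62, against -0.16 without the block), named after its values were seen. No slide held both vectors after 4-OHT. With normexp background 30.9% of 1745 calls were higher and the median of all genes was -0.13; with quantile normalization 35.4% of 1698 were, and with the trend on probe GC content and signal removed, a setting chosen after seeing the data, 55.2% of 2640. The count was 1127 and 308 without control replicate A or B after 4-OHT, and 1353, 603 and 499 without shRNA replicate A, B or C after it. With only the 6 arrays compared it was 1107.

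The vectors' responses to 4-OHT were compared directly. No gene passed the limma interaction test (smallest adjusted p = 0.282; 791 at an unadjusted p under 0.05). The 4 of smallest p, none of which passed, all had negative values: the troponin gene Tnni2 (-0.95, SE 0.13), the lectin-like receptor Klra2 (-1.46, SE 0.21), the ficolin Fcna (-1.13, SE 0.17) and the aminopeptidase Anpep (-0.84, SE 0.13). Klra2 and Fcna were under background before 4-OHT in both vectors, so the size of their values is not measured. Kit had an interaction of 0.38 (adjusted p = 0.656), Hlf 0.51, Itgam -0.49, Egr2 -0.40, Elane 0.23, Csf3r 0.22, Cebpa 0.12, Myc -0.15, Spi1 0.17 and Esr1 0.03. The values of Gfi1 (0.57, adjusted p = 0.332), Cd14 (-0.21) and Mpo (-0.31) are limited by saturated spots, and the tested probes of Csf1r, Adgre1 and Fcgr1 were under background before 4-OHT, so no interaction is given for them. As groups, 5 lists passed camera, with no member past the threshold by itself. Monocyte and macrophage genes (shift -0.18, median -0.14), AU-rich element cytokine genes (shift -0.13, median -0.09) and genes activated by PU.1 (shift -0.18, median -0.18) had more negative changes under 4-OHT in shRNA than in control cells, with camera adjusted p = 0.0224, 0.0224 and 0.0460. By their mean log2 change the monocyte list (2.36 in control and 2.19 in shRNA cells) and the PU.1 list (1.46 and 1.27) rose less in shRNA cells. The median of the monocyte list was higher in shRNA cells (1.36, against 1.23 in control cells). The AU-rich cytokine list fell in both vectors and fell more in shRNA cells (mean log2 change -0.44 in control and -0.57 in shRNA cells). Cholesterol synthesis genes (shift 0.12, median 0.13) and stem and progenitor genes (shift 0.04, median 0.07) fell in both vectors and fell less in shRNA cells, with camera adjusted p = 0.0224 and 0.0460. The cholesterol shift turned to -0.02 with slide as a fixed block. Adjusted over the list alone, 2 stem and progenitor genes passed and no gene of the other 4 lists. With an estimated correlation none of the 5 held, with camera adjusted p = 0.187, 0.359, 0.376, 0.727 and 0.288 in that order. For the monocyte and stem lists the estimate (-0.0098 and -0.024) was below the preset 0.01, so correlation among members does not explain their loss. None of the 5 passed with slide as a fixed block (camera adjusted p = 0.595, 0.144, 0.420, 0.800 and 0.0967 in the same order). The block did not shrink the monocyte, AU-rich cytokine, PU.1 and stem shifts, which were -0.20, -0.22, -0.21 and 0.16 with it. The monocyte and PU.1 shifts were smaller where members under background before 4-OHT were left out. Over the 12076 genes above background on all 12 arrays, a setting chosen after seeing the data, they were -0.10 and -0.06 and did not pass (camera adjusted p = 0.120 and 0.368), while the other 3 lists did. None of these 3 held there with an estimated correlation (adjusted p = 0.504 for AU-rich cytokine, 0.725 for cholesterol and 0.395 for stem genes). With slide as a fixed block the stem list passed camera over these genes (shift 0.18, adjusted p = 0.0377), and the AU-rich cytokine and cholesterol lists did not.

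Across all 15063 genes the responses to 4-OHT in control and shRNA cells correlated with a Pearson coefficient of 0.934 and a Spearman coefficient of 0.827, and the spread of log2 changes in shRNA cells was 0.951 times that in control cells. Of the 6102 and 5770 genes past the threshold, 4839 were shared and 4836 of these had the same direction. The vector differences before and after 4-OHT had coefficients of 0.557 and 0.639 across genes; 48 of the 57 genes passing before also passed after, all in the same direction, and 95.9% of the 2512 had the same sign before 4-OHT. These 2 pairs of comparisons share no array, genes are not independent replicates, and no p is attached to them.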

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

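The tests of slide, of probe GC content, of the depth of knockdown and of members under background, and the breakdown of relabellings by arrays exchanged, were chosen after the result was seen; the regroupings of arrays and the matched random lists were set out before their results were seen. Lists past the threshold of camera at its preset correlation in the interaction, a test of whether the response to 4-OHT differed between vectors, are given here. None of the 5 passed with an estimated correlation (adjusted p = 0.187 to 0.727) or with slide as a fixed block (0.0967 to 0.800), although that block left the monocyte, AU-rich cytokine, PU.1 and stem shifts no smaller (-0.20, -0.22, -0.21 and 0.16) and only the cholesterol shift fell away (-0.02). Monocyte and macrophage genes shifted by -0.18, AU-rich element cytokine and immediate early genes by -0.13, genes known to be activated by PU.1 by -0.18, cholesterol synthesis genes by 0.12, and stem and progenitor genes by 0.0379. Over genes above background on all 12 arrays the monocyte and PU.1 shifts were smaller, at -0.10 and -0.06, and did not pass, while the other 3 lists did. None of these 3 held there with an estimated correlation (camera adjusted p = 0.395 to 0.725). With slide as a fixed block the stem list passed camera over these genes (shift 0.18, adjusted p = 0.0377), and the AU-rich cytokine and cholesterol lists did not. Leaving out 1 array gave between 0 (without control replicate A before 4-OHT, or control replicate C after it) and 8 such lists (without control replicate B before 4-OHT); the count was 3 without shRNA replicate B before 4-OHT or replicate A or B after it, and 2 without shRNA replicate C after it.

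The lower mean response of monocyte and macrophage genes in shRNA cells was set against 4 explanations, and none is excluded. Members under background and a slide difference stay open: over genes above background on all 12 arrays the list shift was -0.10 (camera adjusted p = 0.120), and the interaction of its score per array was -0.0888 with slide as a fixed block (SE 0.05), against -0.20 (SE 0.05) over all members. A response that is smaller for all strongly rising genes stays open, since the list's mean interaction lay at percentile 24.2 of 10000 random lists matched on their mean response to 4-OHT. Chance is not excluded by relabelling vector within treatment, where 5 of 100, the real one included, gave a list shift as large as -0.18 (highest other 0.215), but the other 4 kept or exchanged the vectors of all arrays after 4-OHT and so carry the vector difference itself. A weaker macrophage programme in cells with less Hnrnpa0 may be the reason, as a hypothesis that these tests do not set apart from the other explanations. Effects of the shRNA vector or its clones that do not pass through Hnrnpa0 are not set apart either.

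More genes passed the threshold between vectors after 4-OHT (2512) than before (57), although no gene passed the limma interaction test (791 at an unadjusted p under 0.05). The gap was smaller without adjustment: 5215 genes after and 3361 before had an unadjusted limma p under 0.05. The spread of the vector differences after 4-OHT was 1.11 times that before it. With slide as a fixed block 912 genes had such a p after 4-OHT and 2526 before it. A trend on probe GC content and signal is argued against, since 2640 genes passed after its removal, against 169 before 4-OHT. A slide difference stays open, because no slide held both vectors within a treatment. A fixed slide block links the slides only through control replicate A after 4-OHT and shRNA replicate C before it. It also assumes that slides act alike on all groups. With that block the calls after 4-OHT kept a median of 0.430 of their size, against 0.847 for the calls before it. With slide as a random block 0 genes passed after 4-OHT and 0 before it. The shift between slides 2 and 3 within shRNA cells before 4-OHT, seen through 1 array on slide 3, correlated across genes with the vector difference after 4-OHT (r 0.391). The counterpart between slides 1 and 2 had r -0.0458, and the 1 array on slide 3 also had less Hnrnpa0 than those on slide 2 (-0.75), so the correlation need not come from the slide. A deeper knockdown after 4-OHT may contribute and is not settled, with an interaction of -0.55 for Hnrnpa0 over all arrays and the same difference before and after (-1.38) with slide as a fixed block.

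Splits of the 6 arrays between vectors are too few for a share under 0.05: the real splits gave 57 and 2512 genes and the highest of the other 9 gave 1 each, and 1 of the 10 splits, the real one, reached the real count.

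For the responses to 4-OHT the 10 splits are likewise too few: 6102 and 5770 genes for the real splits, and 5 and 1 for the highest of the others, with 1 split in each at the real count. For the interaction the real count is 0, so the 100 of 100 relabellings that gave as many decide nothing. Some relabellings gave up to 4215 genes, which points to a structure of the arrays: exchanging the vectors in 1 treatment turns the interaction into the summed vector difference.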

How the results depend on the processing

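The removal of the trend on probe GC content and signal, alone and with slide as a random block, and the restriction of list tests to genes above background on all 12 arrays were chosen after seeing the data; the other settings were planned, and the AU-rich motif test with its alternatives was not run. Where a value changed, the cause was not tested unless the setting itself tests fewer genes or arrays. Signal over background limits the dim genes, whose folds are bounds. The 4-OHT counts stayed within 1.5 times their value under all settings except a 2-fold threshold, which left 1567 genes in control and 1436 in shRNA cells, and array weights, which gave 9056 in shRNA cells. Leaving out 1 array gave 5154 to 6410 genes in control and 4647 to 6428 in shRNA cells.

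The count of 57 genes before 4-OHT became 394 with quantile normalization, 2 with normexp background, 10 without the filter on dim probes, 91 with probes above background on 6 arrays, 107 with a floor, 0 with slide as a fixed block and 0 as a random block, 712 with a trended and robust variance, 2657 with array weights, 1 with only the 6 arrays compared (F730002C09Rik, named after its values were seen), 10 with a 2-fold threshold, 169 with the GC and signal trend removed and 12 with that and slide as a random block; leaving out 1 array gave 0 to 496. The count of 2512 after 4-OHT became 358 without the filter, 1 and 0 with slide as a fixed and a random block, 6911 with array weights, 1107 with the 6 arrays compared, 96 with a 2-fold threshold and 48 with the trend removed and slide as a random block; leaving out 1 array gave 308 to 3015. The interaction count of 0 became 2 with slide as a fixed block (Gpr155 and Foxred2), 1 with a trended and robust variance (Tnni2), 99 with array weights and 1 with every probe tested (Cybb); leaving out 1 array gave 0 to 1 (Prlhr without control replicate C after 4-OHT, Adgrl3 without shRNA replicate C before it). Gpr155, Foxred2, Cybb, Prlhr and Adgrl3 are named after their values were seen.

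Whether the replicate letters pair the arrays is not settled: of 12 pairs 5 correlated above 0.1 and 5 had their best partner under the same letter, with values from -0.09 to 0.30. Within a vector the best partner had the same letter for control A (r 0.26) and C (0.20) and shRNA C (0.15). It did not for control B (0.05) or shRNA A (0.07) and B (-0.04). If the letters mark clones, the Hnrnpa0 permutation treats arrays of the same clone as independent. With the replicate block 6248 genes passed in control and 5945 in shRNA cells, 185 before and 2751 after 4-OHT between vectors, and 0 in the interaction; 1 list passed after 4-OHT and 0 in the interaction.

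The Hnrnpa0 difference before 4-OHT, -1.54, was -1.38 with slide as a fixed block (adjusted p = 0.114), -1.57 as a random block (adjusted p = 0.0944) and -1.54 with only the 6 arrays compared (adjusted p = 0.137), and did not pass in these; leaving out 1 array gave -1.76 to -1.30. After 4-OHT, -2.10 became -1.38 (adjusted p = 0.0897) and -1.81 (adjusted p = 0.0527) with the slide blocks; leaving out 1 array gave -2.15 to -2.05. Lists past the threshold numbered 9 and 11 for 4-OHT in control and shRNA cells, 3 after 4-OHT between vectors and 5 in the interaction. With an estimated correlation they were 3, 3, 0 and 0, with fry 17, 20, 8 and 2; quantile normalization gave 5 and 9 for the last pair, and slide as a fixed block 6 and 0. Over genes above background on all 12 arrays 3 lists passed in the interaction, without the monocyte and PU.1 lists, and none did with an estimated correlation (lowest adjusted p = 0.395). The monocyte list lost its call after 4-OHT over these genes (-0.12, camera adjusted p = 0.159). The eosinophil list had no such member and gave no value. Leaving out 1 array gave 0 to 1 before 4-OHT (AU-rich element binding and hnRNP genes, without control replicate B) and 0 to 8 in the interaction. Over genes past the threshold in either comparison the 4-OHT responses of the vectors correlated at 0.969 (against 0.934). The vector differences before and after 4-OHT correlated at 0.865 (against 0.557). In both cases the genes were selected on the values then correlated, which by itself can raise the coefficient. Of the passing genes that the rule selects, only Gjd3 after 4-OHT reversed (-0.30 with slide as a fixed block). Outside it, Foxred2 went from -0.16 to 1.62 after 4-OHT with that block, and Cybb from -0.61 to 1.88 in the interaction with every probe tested. Under the fixed slide block 12 of 12 passing genes that the rule selects before 4-OHT and 43 of 44 after it lost their call without reversing, against 1 of 82 and 3 of 32 for 4-OHT in control and shRNA cells.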

Other observations

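The matched lists for AU-rich element cytokine genes were set out before their result was seen; the slide test of that list was chosen after. Lists that did not pass camera for 4-OHT in control cells were mixed. Of 22 late granulocyte genes 9 rose and 8 fell (also adjusted over the list alone), with the decoy receptor Il1r2 rising at least 37.0-fold, the gelatinase Mmp9 at least 88.1-fold and Cyp4f18 3.58-fold, and the leukotriene receptor Ltb4r1 falling 2.42-fold (median -0.09 and mean 0.49; camera adjusted p = 0.415). Of 25 interferon response genes 10 rose and 4 fell (11 and 6 adjusted over the list alone), among them Gbp2 (5.00-fold), Parp14 (2.29-fold), Irf9 (1.30 in log2) and Usp18 (at least 8.30-fold) upward (camera adjusted p = 0.0513). Of 13 mast cell and basophil genes 2 rose and 4 fell: the interleukin-33 receptor Il1rl1 rose at least 10.4-fold, and the protease Mcpt8, the histamine enzyme Hdc and the transcription factor Gata2 fell 2.15-fold, 3.36-fold and 2.62-fold (median -0.16 and mean 0.02; camera adjusted p = 0.778). Of 23 orthologues of human 5q genes 6 rose and 5 fell, with the matrix protein Tgfbi rising 14.9-fold and Tifab by 1.99 in log2 (median -0.02 and mean 0.33; camera adjusted p = 0.408).

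Lists of other lineages were short and did not pass camera in control cells. Of 6 erythroid genes 2 fell (Klf1 at least 3.89-fold, Epor 2.18-fold; camera adjusted p = 0.415). Of 8 megakaryocyte genes 3 rose and 4 fell (Selp fell 2.36-fold, Treml1 rose at least 6.73-fold; median 0.45, and -0.45 with bounds; adjusted p = 0.985). Of 7 T cell genes 2 fell (Cd28 at least 3.96-fold, Lck 2.43-fold; adjusted p = 0.256). Of 7 B cell genes 3 rose and 2 fell (Blnk rose at least 3.29-fold; median -0.45 and mean 0.54; adjusted p = 0.761). Of 7 dendritic cell and MHC class II genes 4 rose and 1 fell (the invariant chain Cd74 rose at least 4.63-fold; adjusted p = 0.0638). Cell cycle, growth, RNA-binding and stress lists did not pass either. Of 29 G1/S genes 3 rose and 4 fell (adjusted p = 0.770). Of 34 G2/M genes 6 rose (Kif23 1.73-fold; adjusted p = 0.0603). Of 38 ribosome biogenesis and Myc target genes 6 fell (adjusted p = 0.612). Of 11 heat shock genes 1 fell (adjusted p = 0.851). Of 30 AU-rich element binding and hnRNP genes 5 fell and 2 rose (Hnrnpd fell 1.45-fold; adjusted p = 0.534). Of 30 AU-rich element cytokine genes 17 fell and 8 rose (adjusted p = 0.0593). Of 18 p53 targets 4 rose and 4 fell (Trp53inp1 rose 1.78-fold, Gdf15 fell 3.32-fold; adjusted p = 0.471).

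Loss of an AU-rich element binding protein may lower transcripts with such elements, as a hypothesis suggested by the lower AU-rich element cytokine list in shRNA cells after 4-OHT. The list's mean difference, -0.27, lay at percentile 0.01 of 10000 random lists matched on mean signal, so it was lower than that of genes of like signal. The random lists were drawn gene by gene and lack any correlation among the list's members. With an estimated correlation the list did not pass camera (adjusted p = 0.371). A slide difference stays open: the list's score differed by -0.23 (SE 0.06) without a slide term and by -0.11 (SE 0.08) with slide as a fixed block. Before 4-OHT, where Hnrnpa0 was already lower, the score differed by -0.10 (SE 0.06) without the term and by 0.12 (SE 0.08) with it. The list holds genes chosen for known elements and not a scan of transcript sequence, which was not available. Effects of the shRNA vector or its clones that do not pass through Hnrnpa0 were not tested.

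Myc, looked at by array after its values were seen, read lowest in replicate C of both shRNA groups on all 3 of its probes. On the brightest probe it was 4.12 before 4-OHT, against 4.73 and 4.74 in replicates A and B, and 3.61 after it, against 4.04 and 3.99.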
